A study of Homo sapiens with 6 samples.

How the data were processed

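Total RNA of the human ovarian carcinoma cell lines SKOV-3 and Caov-3 was measured on 6 Affymetrix U133 Plus 2.0 arrays, 1 for each line untreated, with IL-6 at 30 ng/ml for 1 h, and with siltuximab (CNTO328) for 4 h followed by IL-6 for 1 h. Per the labels, RNA from 3 flasks was pooled before labelling with biotin, so that an array is 1 sample and a group has no replicate. The dose of siltuximab is not given in the labels used here. Groups were taken from the sample titles and descriptions. The number of arrays limits the precision of every value.

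The deposited values are signal intensities per probe set on a linear scale. Per the submitters' processing notes they were made with Affymetrix Expression Console and MAS5, whose versions are not given in the sources used here. The deposited intensities had been scaled by array, as the mean of each array after trimming 2% of probe sets at each end was about 500 (500.06 to 500.07). No detection calls were used here. Values were taken to log2 after adding a pseudocount of 17.06, the 20th percentile of all deposited values of named probe sets, and no further normalization was applied.

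Of 54675 probe sets, 62 were array controls, 41091 carried 1 gene symbol, 1801 carried several and 11721 carried none. The array annotation gave the symbols, and 41037 probe sets were matched to current gene records by identifier, with 0 symbols changed. A gene was represented by the probe set of highest mean log2 value over the 6 arrays, which gave 19775 genes, and probe sets without a single symbol were left out. A gene entered a comparison of 2 arrays if its higher array was at or above that array's median (percentile 50), and entered the fits over all arrays if at least 2 of the 6 arrays were at or above their median. The GRCh38.p14 gene annotation was used only to name the neighbours of ERBB2. Some list members and an array control are not reported here.

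Within a line, log2 folds of 1 array over 1 array were given without a p-value, with the number of genes at least 2-fold higher and lower and the robust SD (median absolute deviation times 1.4826) of the folds in each of 10 groups of genes by expression. Folds of the 2 lines were compared by Pearson and Spearman correlation across genes and by the number of genes at least 1.5-fold the same way in both lines. That number was set beside the one expected of independent lists. Genes at least 1.5-fold apart with IL-6 in one line were followed in the other line, and their median fold was ranked among 10000 random sets of equal size matched on expression group (seed 20272). Because 2 comparisons of a line share an array, the correlation that noise alone gives them was simulated. The noise of all arrays of a line was taken from the spread of its folds of siltuximab plus IL-6 over untreated, which leaves out the IL-6 array.

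Over both lines, limma 3.58.1 in R 4.3.3 was fitted to all 6 arrays with line and treatment as factors and a trended prior variance, leaving 2 residual degrees of freedom. The residual of that fit is how treatment effects differ between the lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, over all genes and again over each gene list alone. The adjustment over a list alone was not corrected for the number of lists and comparisons. The 2 lines were compared in the same fit with treatment as a block, 3 arrays of each, which are 3 treatments and not replicates. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes and with an estimated one, and p-values were adjusted over the lists. The estimated correlation rests on the 2 residual degrees of freedom, so that a call lost with it may reflect low power. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

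The 19 gene lists covered early response genes of IL-6 and STAT3, STAT3 survival and growth targets, immediate early genes, NF-kB targets, interferon-stimulated genes, acute phase proteins, IL-6 receptor and signalling genes, cell cycle, hypoxia and glycolysis, unfolded protein and amino acid stress, heat shock, sterol synthesis, drug transport and paclitaxel resistance, epithelial, mesenchymal and identity markers, leukocyte markers, fibroblast and endothelium markers, and reference genes. Only members past the filter were counted. Each list's median fold in a line was ranked among 10000 random lists matched on expression group, as a description of these arrays.

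Genes to be named in the text were fixed by rule. The rule took, per line and for IL-6 and for siltuximab, the 8 genes with the largest fold in each direction, and for both lines together the 10 in each direction with the largest smaller fold. It also took the 4 members of each list with the largest mean fold, any gene called by limma for a treatment, the 10 genes in each direction and the 4 members of each list that differed most between the lines, and a fixed set that included SOCS3, JUNB, FOS, MYC, STAT3, ERBB2 and CDKN2A. Not every gene that the rule allows is named. The neighbours of ERBB2 and the genes called without the Caov-3 IL-6 array were chosen after their values were seen.

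The comparisons, lists, naming rule and most of the tests and alternatives were chosen before the data were examined. Alternatives were no pseudocount, a pseudocount of the median (111), no filter, a filter at percentile 75, quantile and cyclic loess normalization, the mean of all probe sets of a gene, leaving out probe sets with names ending in _x_at or _s_at, a 2-fold threshold, and limma without a trend, without the line block, without the treatment block and with each treatment left out in turn. Added after seeing the data were the fits without the Caov-3 IL-6 array, the numbers of genes that stood opposite ways, and expected numbers matched on expression in both lines. So were the tests on exchanged lines, on further probe sets, on the ACTB ratio and on other splits of the arrays.

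The limma fit for IL-6, camera with the preset correlation, the random sets and the number of genes the same way in both lines were tested on simulated data. The other fits and counts were not. For IL-6 over both lines, with 200 of 12290 genes changed and spreads drawn from the fitted prior, limma recovered 0% of 1.5-fold, 43.1% of 2-fold and 90.2% of 4-fold changes, with 0%, 3.4% and 4.7% of calls false. With each gene's moderated spread it recovered 30.1%, 76.1% and 97.1%, with 15.2%, 11.1% and 9.5% of calls false. Camera with the preset correlation called a list of 20 genes shifted by 0.5 in 20 of 20 draws and an unshifted list in 0 of 20. Here and for the random sets below, simulated genes varied independently and list members were drawn at random. These rates therefore need not hold for lists whose genes vary together.

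For the random sets, 20 draws of 2 lines were made with 2000 sets each. On unchanged arrays the IL-6 genes followed in the other line fell outside the central 95% of random sets in 1 of 40 tests, and with siltuximab in 2 of 40. For 2 lists of unchanged genes this was so in 1 and 4 of 40 with IL-6 and in 2 and 4 of 40 with siltuximab. With 200 genes shifted alike in both lines, the followed genes and a list shifted by 0.5 lay outside in 40 of 40, and an unshifted list in 0 of 40 with IL-6 and 1 of 40 with siltuximab. On unchanged arrays 23.6 genes stood the same way in both lines, where independent lists gave 6.3 and matching on expression gave 22.4.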

Results

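RNA was measured in 2 human ovarian carcinoma cell lines, SKOV-3 and Caov-3, on 6 Affymetrix U133 Plus 2.0 arrays. Each line was left untreated, given 30 ng/ml of interleukin-6 (IL-6) for 1 h, or given the anti-IL-6 antibody siltuximab for 4 h and then IL-6 for 1 h. IL-6 signals through its receptor and gp130 (IL6ST) to the transcription factor STAT3, whose early targets include the feedback inhibitor SOCS3. Each of the 6 groups had 1 array, hybridised with RNA pooled from 3 flasks, so that no difference within a line had a replicate check. The number of arrays limits the precision of every value, and no sample with the antibody alone was analysed here.

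The arrays had been scaled alike, with a 2% trimmed mean of 500.06 to 500.07 on each, and the median signal of all probe sets ran from 72.8 to 89.8. Arrays of the same line correlated at r = 0.976 to 0.984 across genes, and arrays of different lines at 0.878 to 0.886. The control probe sets for beta-actin (ACTB), a transcript used to follow RNA integrity, gave a 5' to 3' signal ratio of 0.494 on the Caov-3 IL-6 array and of 0.643 to 0.766 on the other 5. GAPDH had a ratio of 1.05 on the Caov-3 IL-6 array, within the range of 0.957 to 1.07 of all 6. The control probe set for the middle of 28S ribosomal RNA was at 887 on the Caov-3 IL-6 array and at 2382 to 3307 on the other 5. That array also held 207 genes at least 2-fold below both other Caov-3 arrays, where the highest such count on another array was 23. The poly-A control transcripts added to the RNA before labelling (12 probe sets) stood at 1.52 times the untreated level on the SKOV-3 IL-6 array and at 1.49 times on the Caov-3 IL-6 array, against 1.02 and 1.17 times on the siltuximab arrays.

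**Figure D1:**
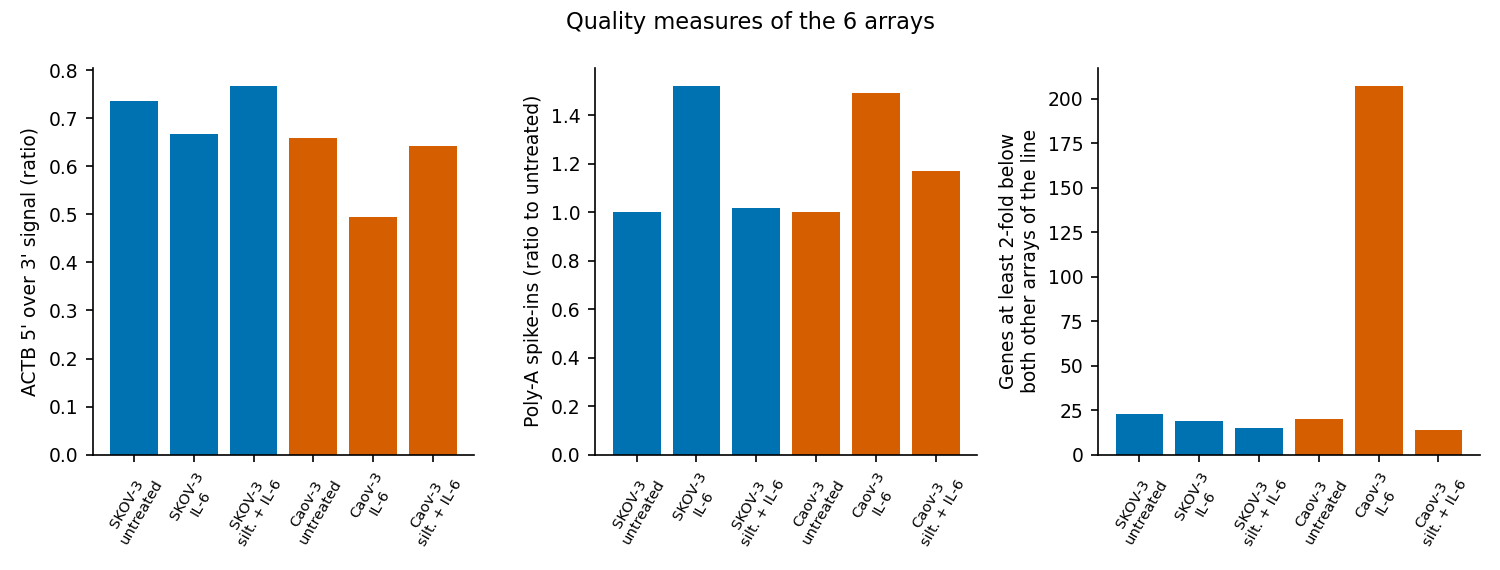
Bars give, for each of the 6 arrays, the ACTB 5' to 3' signal ratio, the geometric mean of the poly-A control signals as a ratio to the line's untreated array, and the number of genes at least 2-fold below both other arrays of the same line. The Caov-3 IL-6 array has the lowest ACTB ratio, 0.494, and the highest number of such genes, 207.

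The first question was what 1 h of IL-6 did in SKOV-3. SOCS3, the STAT3-induced inhibitor of the same receptor, was at 1602 with IL-6 and 1159 without, a log2 fold of 0.46. Its further probe sets were at -0.23, 0.47 and 0.73. STAT3 itself, which its own protein induces, was at 2527 against 1330, a log2 fold of 0.92 (its 3 further probe sets were at 0.70, -0.07 and 0.00), and the AP-1 gene JUNB at 530 against 341, a log2 fold of 0.61. Other early STAT3 targets lay nearer to their untreated level, with PIM1 at 0.20, FOS at 0.15, CEBPD at 0.09 and MYC at -0.21. The survival genes MCL1, BCL2L1 and BIRC5 were at -0.15, -0.23 and -0.06. ABCC3, an efflux pump for organic anions and some drugs, was at 323.5 with IL-6 and 613 without, a log2 fold of -0.89.

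Among 11411 genes in SKOV-3, 74 were at least 2-fold higher and 163 at least 2-fold lower with IL-6. The share upwards was 31.2%, and ran from 30.6% with the mean of all probe sets to 80% with a filter at the 75th percentile, where 12 were higher and 3 lower. The untreated SKOV-3 array, which these folds share with those of siltuximab plus IL-6 against untreated, held 64 genes at least 2-fold above both other arrays of its line, and the other 5 arrays held 12 to 31. Among the largest folds were those of TASL, an adaptor of endosomal Toll-like receptors, at 2.32, NACA4P, a pseudogene of a translation-associated chaperone, at 2.24, IL4I1, a secreted amino acid oxidase, at 2.17 and the potassium channel gene KCNQ3 at 2.16. NACA4P alone of these had a high signal, 19946 against 4221, on a probe set that can also detect related sequences, whereas TASL went from 11.6 to 125.9. The largest folds downwards included those of the transcript DKFZP434A062 at -2.76, the drug-metabolising enzyme CYP3A4 at -2.60, the endosomal sodium exchanger SLC9A9 at -2.60 and the matrix protease MMP19 at -2.43. Of the 237 genes at least 2-fold apart, 228 lay below the median in expression, where folds scattered most (robust SD of 0.531 to 0.666 in the lowest of 10 expression groups and 0.102 to 0.199 in the highest, over the IL-6 and siltuximab comparisons of both lines).

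In Caov-3 the same treatment gave SOCS3 at 845 against 594, a log2 fold of 0.50, close to the 94th percentile of genes of its expression (percentile 93.8). Its further probe sets were at 0.01, -0.94 and 0.79. STAT3 stood the other way from SKOV-3, at 832 against 2521, a log2 fold of -1.58, and its 3 further probe sets were at -1.40, -1.43 and -1.10. JUNB was at 0.18, PIM1 at -0.22, CEBPD at -0.13 and FOS at -0.10. Chemokine CXCL3, an NF-kB target that draws neutrophils, was at 437 against 211, a log2 fold of 0.99, while NFKB2, a subunit gene of NF-kB, was at -1.29 and the adhesion gene ICAM1 at -0.67. The kinase SRC, which phosphorylates STAT3, went from 23.9 to 288.3, a log2 fold of 2.90, the largest upwards.

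Other genes far above their untreated level in Caov-3 were PLEKHA6 at 2.71, a junction protein gene, the kinase CDK18 at 2.40 and the kinase FES at 2.36. The largest folds downwards included those of PMS2P2, a mismatch repair pseudogene, at -3.79, the nuclear matrix protein MATR3 at -3.65, the interferon-induced IFI6 at -3.34, the T-cell regulator FOXP3 at -3.01 and the Golgi gene COG7 at -2.81. IFI6 was low on this array alone, with 4495 untreated, 428 with IL-6 and 6350 with siltuximab and IL-6, and MATR3 with 673, 38.1 and 821. Among 11862 genes, 128 were at least 2-fold higher and 336 at least 2-fold lower, so that 27.6% of these folds were upwards, against 44.8% (226 higher and 279 lower) after quantile normalization and 41.1% (202 and 290) after cyclic loess. It was 9.3% (20 and 195) with a pseudocount of the median, 15.8% (22 and 117) with a filter at the 75th percentile and 16.7% (74 and 370) with the mean of all probe sets. Of the 464 genes, 406 lay below the median in expression, and all folds of this paragraph rest on the array with the low ACTB ratio.

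**Figure D2:**
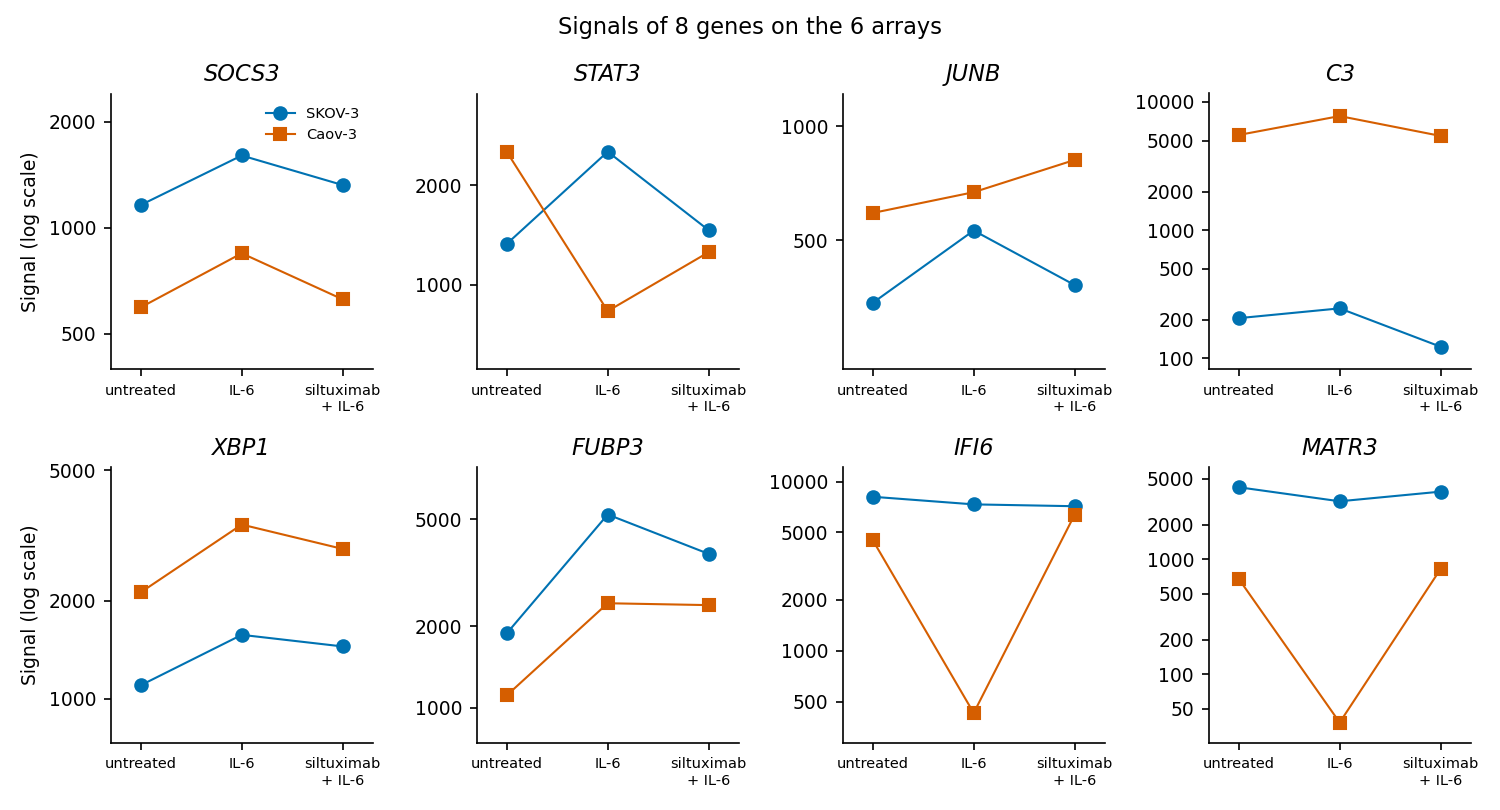
Signals on a log scale of 8 genes on the untreated, IL-6, and siltuximab plus IL-6 arrays of SKOV-3 (circles) and Caov-3 (squares), 1 array per point. SOCS3, C3, XBP1 and FUBP3 are highest on the IL-6 array in both lines, and IFI6 and MATR3 are far lower only on the Caov-3 IL-6 array, at 428 and 38.1.

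The genes that stood the same way in both lines were sought next, since the 2 folds share no array. The poly-A controls were nevertheless above untreated on both IL-6 arrays, at 1.52 times in SKOV-3 and 1.49 times in Caov-3. A difference in handling common to the IL-6 arrays could thus move genes alike in both lines and was not tested. FUBP3, a relative of an activator of MYC, was at log2 folds of 1.45 in SKOV-3 and 1.12 in Caov-3, the Golgi gene BLZF1 at 1.14 and 1.40, the SUMO-like protein gene NFATC2IP at 0.87 and 1.05, ACSL4, an enzyme of arachidonic acid activation, at 0.95 and 0.85, and the COPII coat gene SEC24D at 0.85 and 0.83. FUBP3 went from 1887 to 5197 in SKOV-3 and from 1111 to 2437 in Caov-3. Dimmer genes the same way were KCNIP3 at 1.74 and 1.81, the matrix gene TNXB at 1.49 and 1.40 and TSPAN32 at 1.16 and 1.75. Downwards in both lines were the small nucleolar RNA SNORA78 at -2.18 and -1.90, LINC01016 at -2.14 and -1.44, the acetylcholine receptor subunit CHRNB2 at -1.15 and -1.68, the BCL2-binding chaperone FKBP8 at -1.12 and -2.52 and the MYC-induced factor TFAP4 at -1.47 and -0.92. Probe sets of 1 gene often differed: the second probe set of FUBP3 was at 0.43 in SKOV-3 and at -2.16 in Caov-3. Further probe sets of BLZF1 were at 0.61, 0.62 and 0.08 in SKOV-3 and at -0.49, -0.80 and 0.90 in Caov-3. With the mean of all probe sets the Caov-3 folds turned to -0.52 for FUBP3, -0.56 for NFATC2IP and -1.10 for ACSL4, which was at -1.66 without probe sets ending in _x_at or _s_at.

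Of 10537 genes, 41 were at least 1.5-fold higher in both lines and 40 at least 1.5-fold lower in both, 81 together, where independent lists would share 33.6. Matching genes on their expression in both lines raised that expected number to 54.6, of which 18.7 were expected upwards and 35.9 downwards. The number of genes that stood opposite ways was 92, with 31.6 expected of independent lists and 58.0 after matching. Folds of the 2 lines correlated at r = 0.04 (Spearman 0.142) across genes, which are not independent of each other. With the mean of all probe sets the correlation turned to -0.094 (Spearman -0.036), with 49 genes the same way and 83 opposite ways. With a filter at the 75th percentile it was 0.123 (Spearman 0.245), with 27 the same way and 19 opposite ways. Over both lines limma called 0 of 12290 genes for IL-6 (1182 at an unadjusted p under 0.05), with 0.234 as the smallest adjusted p, held by FUBP3 among others (log2 difference 1.29, SE 0.131). Without the Caov-3 IL-6 array, where IL-6 stands on SKOV-3 alone and 1 residual degree of freedom is left, limma called 3 genes, namely NACA4P at 2.14 (adjusted p 0.00226), FUBP3 at 1.49 (0.00598) and BCL7C at -1.85 (0.0205), a fit chosen after its values were seen. Folds of the 2 brightest probe sets of a gene correlated at 0.121 in SKOV-3 and 0.104 in Caov-3.

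**Figure D3:**
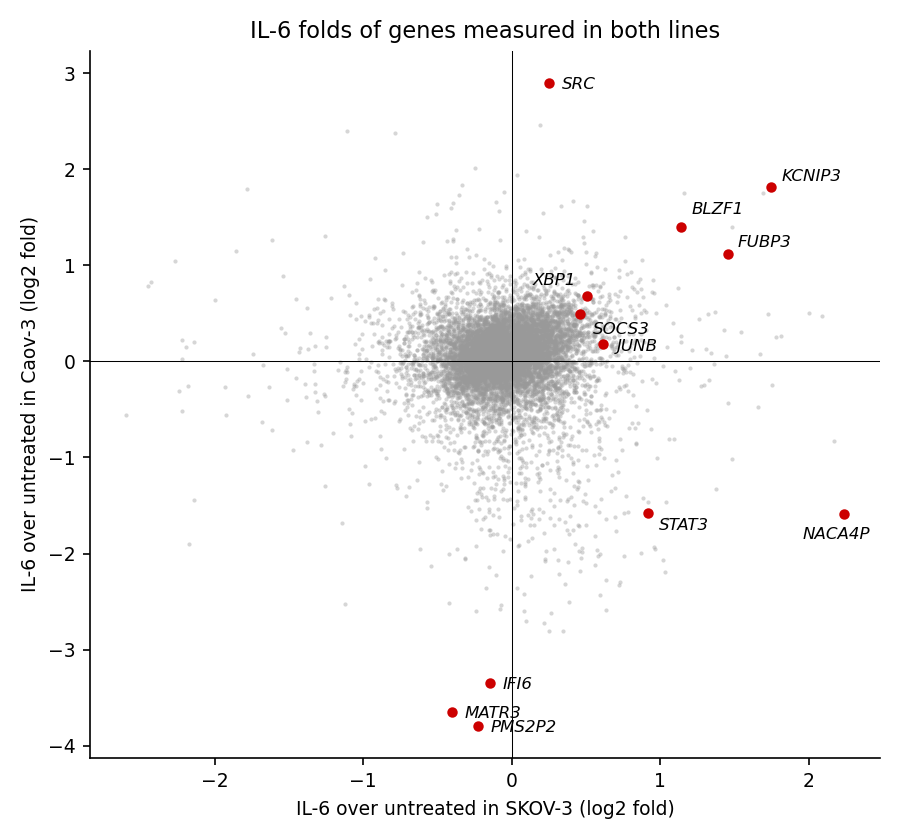
Each point is 1 gene measured in both lines, with its log2 fold of IL-6 over untreated in SKOV-3 across and in Caov-3 upwards. FUBP3, BLZF1 and KCNIP3 lie at the upper right, STAT3 and NACA4P stand opposite ways in the 2 lines, and IFI6, MATR3 and PMS2P2 are low only in Caov-3 (r = 0.04 over 10537 genes).

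The early response list of IL-6 and STAT3 had a median log2 fold of 0.08 in SKOV-3 (12 of 19 genes higher), at percentile 97.2 of 10000 random lists matched on expression, and of -0.01 in Caov-3 (9 of 18 higher), at percentile 11. STAT3 survival and growth targets stood at -0.13 and 0.09 (percentiles 18.2 and 52.7), with CCND1, which drives entry into the cell cycle, at 0.17 and 0.33 and BCL2 at 0.51 and -0.62. Immediate early genes were at -0.10 and 0.18 (22.4 and 92.2), with the matricellular CCN1 at 0.02 and 0.48, and NF-kB targets at -0.12 and 0.17 (10.9 and 90.7), with the prostaglandin synthase PTGS2 at 0.34 and 0.39. Receptor and signalling genes were at -0.08 and 0.04 (35.5 and 26.9), with IL6ST at -0.20 and -0.12, and turned to 0.088 and -0.081 with the mean of all probe sets. Interferon-stimulated genes lay at -0.12 in SKOV-3 (percentile 21.6) and at -0.09 in Caov-3 (0.44), where 11 of 19 were lower, among them OAS1 and OAS3, sensors of viral RNA, at -0.48 and -0.31. All of these lists had 0 genes past the limma test over all genes and 0 when adjusted over the list alone, with smallest list-adjusted p of 0.116, 0.312, 0.599, 0.169, 0.458 and 0.0946 in the order named.

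Genes of the unfolded protein and amino acid stress list were at a median of -0.01 in SKOV-3 and 0.12 in Caov-3 (percentiles 75.2 and 74.7). Within it XBP1, the transcription factor of the unfolded protein response, rose with IL-6 in the limma fit when adjusted over the list alone (log2 difference 0.59, SE 0.106, list-adjusted p 0.0151, with 0.51 in SKOV-3 and 0.68 in Caov-3, but with -0.26 in SKOV-3 from the mean of all its probe sets), and the endoplasmic reticulum chaperone HSP90B1 fell in the same test by 0.41 (SE 0.0977, list-adjusted p 0.0376). The list therefore had 1 gene higher and 1 lower when adjusted over the list alone and 0 over all genes. DDIT3, a stress transcription factor, was at 0.16 and 0.67, and the cystine transporter SLC7A11 at 0.20 and 0.55, and neither passed when adjusted over the list. Hypoxia and glycolysis genes had medians of -0.10 and 0.01 (percentiles 26.1 and 15.9), with 1 gene lower when adjusted over the list alone, the glycolytic enzyme ALDOA (log2 difference -0.33, list-adjusted p 0.0469), and 0 over all genes.

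Reference genes were at -0.16 in SKOV-3 (percentile 10.1) and -0.14 in Caov-3 (0.37), and 5 of 11, among them GAPDH, ACTB and B2M, were lower when adjusted over the list alone (smallest list-adjusted p 0.0285) with 0 over all genes. ACTB had a log2 difference of -0.33 and GAPDH of -0.37 in the scaling as deposited, of -0.27 and -0.32 after cyclic loess, but of -0.05 and -0.12 after quantile normalization, so that the size of these differences depended on the scaling. The median of the reference list over both lines was -0.15 as deposited, 0.02 after quantile normalization and -0.15 after cyclic loess. Leukocyte markers (4 genes near the detection limit, among them LCP1 at -1.46 and CD79A at -0.87) were at -0.78 in SKOV-3 (percentile 2.74) and 0.02 in Caov-3 (45.2). They were lower over both lines in limma's camera test with a preset correlation (adjusted p 0.0364), a call lost with an estimated correlation (adjusted p 0.953) and without the Caov-3 IL-6 array (0.133). Fibroblast and endothelium markers were at -0.15 and -0.12 (31.8 and 11.9), with the endothelial PECAM1 at -1.76 in Caov-3.

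The other lists gave no call over all genes and none when adjusted over the list alone. Acute phase proteins (5 genes) were at -0.49 in SKOV-3 (percentile 1.02) and 0.21 in Caov-3 (90.1), where the iron carrier LCN2 was at -0.49 and 0.21 and the complement gene C3 at 0.24 and 0.49. Drug transport and paclitaxel resistance genes were at -0.20 and 0.15 (3.42 and 81.6), with ABCC3 lowest in SKOV-3 and the tubulin regulator STMN1 at 0.52 in Caov-3. Heat shock genes were at -0.18 and -0.08 (7.92 and 4.34), 0 of 9 being higher in SKOV-3, where the median was -0.023 after quantile normalization and -0.045 after cyclic loess, with the collagen chaperone SERPINH1 at -0.35 and -0.17. Sterol synthesis genes were at -0.13 and 0.08 (9.95 and 43.9) and cell cycle genes at -0.04 and 0.08 (71 and 52.6) with TOP2A at 0.18 and 0.60. The cell cycle median in SKOV-3 was 0.028 after quantile normalization, and with the mean of all probe sets the Caov-3 medians turned to -0.258 for sterol synthesis and -0.101 for cell cycle genes. Epithelial markers were at -0.20 and 0.06 (3.98 and 42.4) and mesenchymal markers at -0.11 and 0.06 (25.8 and 44.8). The identity genes of the lines were at -0.12 and 0.11 (31.3 and 54.5), with the tumour suppressor SMAD4 at 0.40 and 0.11. With the mean of all probe sets the Caov-3 folds of CCND1, SLC7A11, STMN1 and TOP2A turned to -0.35, -0.42, -0.41 and -0.49.

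Whether siltuximab before IL-6 moved these genes back was asked by setting the siltuximab plus IL-6 array against the IL-6 array. In SKOV-3 SOCS3 was at 1321 with the antibody and 1602 without, a log2 fold of -0.28, STAT3 at -0.78, JUNB at -0.46, PIM1 at -0.42 and FOS at -0.33. Further probe sets of SOCS3 were at -0.10, 0.05 and -1.23. The complement gene C3 was at 123 against 245, a log2 fold of -0.90, and ELF3, an epithelial transcription factor induced by inflammatory signals, at 148 against 275, a log2 fold of -0.82. ABCC3 was at 0.00 and MCL1 was at 0.02. Large folds upwards were those of SPATA21 at 2.48, CYP3A4 at 2.22, the haemoglobin chaperone AHSP at 2.20 and NUDT10 at 1.97, and downwards those of GTF2IP20, a pseudogene, at -2.69, TASL at -2.35, the adenosine receptor ADORA1 at -2.10, MXRA8 at -2.07 and the junction gene JAM3 at -2.05. Among 11238 genes 56 were at least 2-fold higher and 61 at least 2-fold lower, 116 of the 117 below the median in expression.

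In Caov-3 SOCS3 was at 625 with the antibody and 845 without, a log2 fold of -0.42, PIM1 at -0.42, C3 at -0.51 (5433 against 7759) and ELF3 at -0.50 (469 against 671). Further probe sets of SOCS3 were at -0.37, 0.85 and -1.02. STAT3 was at 0.58 and NFKB2 at 1.37, both back towards their untreated level, and JUNB was at 0.28. Without probe sets ending in _x_at or _s_at NFKB2 was at -0.46. The largest folds upwards included MATR3 at 3.93, IFI6 at 3.84, PMS2P2 at 3.53, the zinc finger gene ZNF431 at 3.08, AGAP9 at 2.98 and the translation factor gene EIF3C at 2.68, all genes that were low on the IL-6 array. Downwards stood IGF2-AS at -2.29, the globin NGB at -2.23, SAMD5 at -2.21 and the scavenger receptor STAB1 at -2.08. Among 11829 genes 280 were at least 2-fold higher and 86 at least 2-fold lower, 76.5% upwards, against 55.2% (912 and 739) with no filter, 65.5% (234 and 123) after quantile normalization and 96% (143 and 6) with a pseudocount of the median. Of the 366 genes, 318 lay below the median in expression.

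Genes of both lines that stood the same way with siltuximab included the pseudogene RRN3P3 at 1.17 in SKOV-3 and 0.94 in Caov-3, LINC01016 at 1.08 and 1.06, the tumour suppressor WWOX at 1.03 and 0.79, NFATC4 at 1.02 and 0.71 and FKBP8 at 0.78 and 2.08. Downwards were CCDC138 at -0.77 and -0.97, the channel gene PANX2 at -0.85 and -0.83 and PRKACA, the catalytic subunit of protein kinase A, at -0.73 and -1.04. Together 16 genes were at least 1.5-fold higher and 12 at least 1.5-fold lower in both lines, 28 of 10447, with 12.8 expected of independent lists and 24.6 after matching on expression. Opposite ways stood 63 genes, with 13.4 and 29.6 expected, and the folds of the 2 lines correlated at r = -0.09 (Spearman -0.047). No gene of 12290 passed the limma test over both lines, where 398 had an unadjusted p under 0.05 and the smallest adjusted p was 0.983.

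FUBP3, BLZF1 and the other genes at least 1.5-fold apart in 1 line were then followed in the other line, which shares no array with their selection. This does not remove a difference in handling common to the IL-6 arrays of both lines, which the poly-A controls leave possible. The genes at least 1.5-fold higher with IL-6 in SKOV-3 had a median log2 fold of 0.15 with IL-6 in Caov-3, where 263 of them were measured. This lay at percentile 99.9 of matched random sets, whose median was 0.07. With siltuximab in Caov-3 the selected genes measured were at -0.01 where random sets were at -0.08 (percentile 99.8), and against untreated at 0.13 (percentile 100). The 442 genes higher with IL-6 in Caov-3 were at 0.08 with IL-6 in SKOV-3 (percentile 100, random sets at -0.05), at 0.02 with siltuximab (82.8) and at 0.10 against untreated (100). Relative to all genes, the siltuximab medians were 0.076 for the SKOV-3 genes and 0.007 for the Caov-3 genes. Their sign turned under other settings, to -0.026 at a 2-fold threshold for the former, and to -0.023 with no filter and -0.006 with a filter at the 75th percentile for the latter. The 392 genes lower in SKOV-3 were at 0.00 in Caov-3 with IL-6 (percentile 0.18, random sets at 0.07), -0.05 with siltuximab (83.4) and -0.05 against untreated (0.09). The 607 genes lower in Caov-3 were at 0.03 in SKOV-3 with IL-6 (100, random sets at -0.05), -0.10 with siltuximab (0) and -0.06 against untreated (4.85). Not all selected genes were measured in each comparison, and 263, 442, 392 and 607 are those measured with IL-6 in the other line. In the order named, 259, 426, 386 and 596 were measured with siltuximab and 257, 439, 378 and 606 against untreated.

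Within a line the IL-6 fold and the siltuximab fold share the IL-6 array, whose noise alone opposes them. In SKOV-3, where STAT3 and JUNB followed that opposite course, the 2 folds correlated at r = -0.499 over genes, with -0.503 simulated for unchanged genes, and had a covariance of -0.0376 beside a simulated -0.0361. In Caov-3, where IFI6 and MATR3 did so, the correlation was -0.76 beside a simulated -0.487, and the covariance was -0.113 beside -0.0313. The folds of IL-6 and of siltuximab plus IL-6 over the same untreated array correlated at 0.633 in SKOV-3 (0.495 simulated, covariance 0.0535 beside 0.0353) and at 0.494 in Caov-3 (0.503 simulated, covariance 0.055 beside 0.0326). Genes in these correlations are not independent, and part of each value may come from the shared array. The simulated noise was taken from folds without the IL-6 array. Greater noise on the Caov-3 IL-6 array is therefore not in the simulated values and could itself part them from the measured ones.

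In SKOV-3 the early response list of IL-6 and STAT3 was at a median of -0.13 with siltuximab, 15 of its 19 genes being lower, at percentile 0.1 of matched random lists, while in Caov-3 it was at -0.07 (65.8), with 11 of 18 lower. The list's IL-6 fold in SKOV-3 rests on the same IL-6 array, so that high values on that array would give both. Interferon-stimulated genes were at 0.03 in SKOV-3 (percentile 71.4) and at 0.21 in Caov-3 (percentile 100), where 15 of 19 were higher, among them OAS1 at 0.61, OAS3 at 0.57, IFI44L at 0.51 and ISG15, a ubiquitin-like modifier, at 0.21. They were higher over both lines in limma's camera test with a preset correlation (adjusted p 0.00998), a call lost with an estimated correlation (adjusted p 0.991) and without the Caov-3 IL-6 array (0.625). Survival and growth targets of STAT3 were at 0.04 and 0.00 (67.8 and 94.8), immediate early genes at 0.01 and -0.10 (43.3 and 47.9), NF-kB targets at 0.05 and -0.06 (79.9 and 72.1) and receptor and signalling genes at -0.01 and 0.01 (35.1 and 94.5). Acute phase proteins were at 0.22 and -0.21 (93.2 and 7.38). Of them C3 fell by 0.71 in the limma fit when adjusted over the list alone (SE 0.168, list-adjusted p 0.025), 1 gene lower, with 0 over all genes.

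The remaining lists had 0 genes past either adjustment with siltuximab. Cell cycle genes were at 0.04 in SKOV-3 and -0.13 in Caov-3 (percentiles 83.7 and 21.9), with the mitotic kinase gene CDK1 at 0.03 and -0.58, and hypoxia and glycolysis genes at -0.01 and -0.12 (27.3 and 33.3), with the hexokinase HK2 at -0.31 and -0.35. Unfolded protein and amino acid stress genes were at -0.02 and -0.12 (15.8 and 26.3), where XBP1 was at -0.12 and -0.25 (0.24 in Caov-3 with the mean of all its probe sets). Heat shock genes were at 0.07 and 0.00 (88.9 and 93.4), sterol synthesis genes at 0.05 and -0.14 (76.4 and 31.6), and drug transport and paclitaxel resistance genes at 0.06 and -0.19 (83.5 and 6.92). With the mean of all probe sets the Caov-3 medians of the last 2 lists were 0.25 and 0.031. Epithelial markers were at -0.06 and -0.10 (12.4 and 41.4), mesenchymal markers at -0.01 and 0.02 (29.6 and 88.7) and the identity genes at -0.08 and -0.11 (17.9 and 43.7). Leukocyte markers were at 0.21 and -0.16 (79.4 and 30.1), fibroblast and endothelium markers at -0.30 and 0.14 (11 and 89.5), and reference genes at -0.04 and 0.07 (10.1 and 99.4).

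Setting siltuximab plus IL-6 against untreated cells asked what the antibody left. IFIT2, an interferon-induced inhibitor of translation, rose when adjusted over the interferon list alone (limma log2 difference 0.60, SE 0.11, list-adjusted p 0.0198, with 0.41 in SKOV-3 and 0.78 in Caov-3). In Caov-3 17 of 19 interferon-stimulated genes were higher than untreated (median 0.11, percentile 99.95), and in SKOV-3 14 of 19 were lower (median -0.11, percentile 7.8). The early response list of IL-6 and STAT3, here without the IL-6 arrays, was at -0.07 in SKOV-3 (percentile 24.8) and -0.02 in Caov-3 (42.1). SOCS3 was at 0.19 in SKOV-3 and 0.07 in Caov-3, XBP1 at 0.39 and 0.44, and ABCC3 at -0.88 in SKOV-3. The IL-6 fold of ABCC3 rests on the same untreated SKOV-3 array, so that 1 high untreated value would give both. Reference genes were at -0.22 and -0.15, and 2 of them, ACTB at -0.30 and GAPDH at -0.38, were lower when adjusted over the list alone (smallest list-adjusted p 0.0279), and were at -0.02 and -0.14 after quantile normalization and at -0.20 and -0.30 after cyclic loess. In SKOV-3 62 genes were at least 2-fold higher and 153 lower, and in Caov-3 57 and 66. With a filter at the 75th percentile these were 6 and 2 in SKOV-3 and 6 and 3 in Caov-3. A pseudocount of the median gave 7 and 14 in SKOV-3 and 11 and 7 in Caov-3. By 1.5-fold 54 genes stood the same way in both lines (11 expected of independent lists, 31.2 after matching) and 39 opposite ways (11.3 and 30). limma called 0 genes over both lines, with 705 at an unadjusted p under 0.05 and 0.521 as the smallest adjusted p, and 3 genes without the Caov-3 IL-6 array, where FUBP3 was at 1.03 (adjusted p 0.011).

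The 2 lines were then set against each other, with 3 arrays of each, which held 3 treatments and were not replicates of 1 condition. Epithelial genes were far higher in Caov-3, with E-cadherin (CDH1) at a log2 difference of 7.17 (SE 0.176, limma adjusted p 3.27e-07), keratin KRT19 at 7.80 (SE 0.346), the splicing regulator ESRP1 at 6.63, and the mucin MUC1 at 5.91. Mesenchymal markers were split, with 5 of 11 higher and 6 lower in Caov-3. Of them VIM at -7.34 (SE 0.101, limma adjusted p 9.75e-08) and ZEB1, a repressor of CDH1, at -5.47 were lower, and so was the caveola gene CAV1 at -3.43. VIM had a mean signal of 22924 ± 2524 (SD, n = 3) in SKOV-3 and of 126 ± 27.8 in Caov-3. Genes of IL-6 signalling differed too: IL6 had 666 ± 121 in SKOV-3 and 3620 ± 106 in Caov-3, while its receptor IL6R had 802 ± 68.8 in SKOV-3 and 41.6 ± 17.6 in Caov-3. LIFR, receptor of a related cytokine, was lower in Caov-3 by a log2 difference of -3.36, and IL6ST and SOCS3 were each at -0.97.

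Tumour genes separated the lines as well. RB1, which restrains entry into the cell cycle, had 1967 ± 321 (SD, n = 3) in SKOV-3 and 1.9 ± 0.8 in Caov-3, and CDKN2A, whose protein acts through RB1, had 110.5 ± 56.1 and 4182 ± 127. MYC had 20035 ± 1749 in SKOV-3 and 925.5 ± 38 in Caov-3. ERBB2, known to be amplified in SKOV-3, had 654 ± 76.5 on the arrays labelled SKOV-3 and 1109 ± 119 on those of Caov-3 (log2 difference 0.75, limma adjusted p 0.002, but 0.34 and not called with the mean of all its probe sets). The largest differences towards Caov-3 were those of the hormone SST at 9.93, the protease inhibitor TFPI2 at 9.21, SPINK6 at 9.03, ARMCX2 at 8.86 and EFEMP1 at 8.72, and towards SKOV-3 those of the collagen-modifying enzyme P3H2 at -8.60, the growth factor PDGFC at -7.98 and the thrombin receptor F2R at -7.97. limma called 8707 of 12290 genes, 4741 higher and 3966 lower in Caov-3, and 2 probe sets of a gene correlated at 0.865 over 6161 genes.

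**Figure D4:**
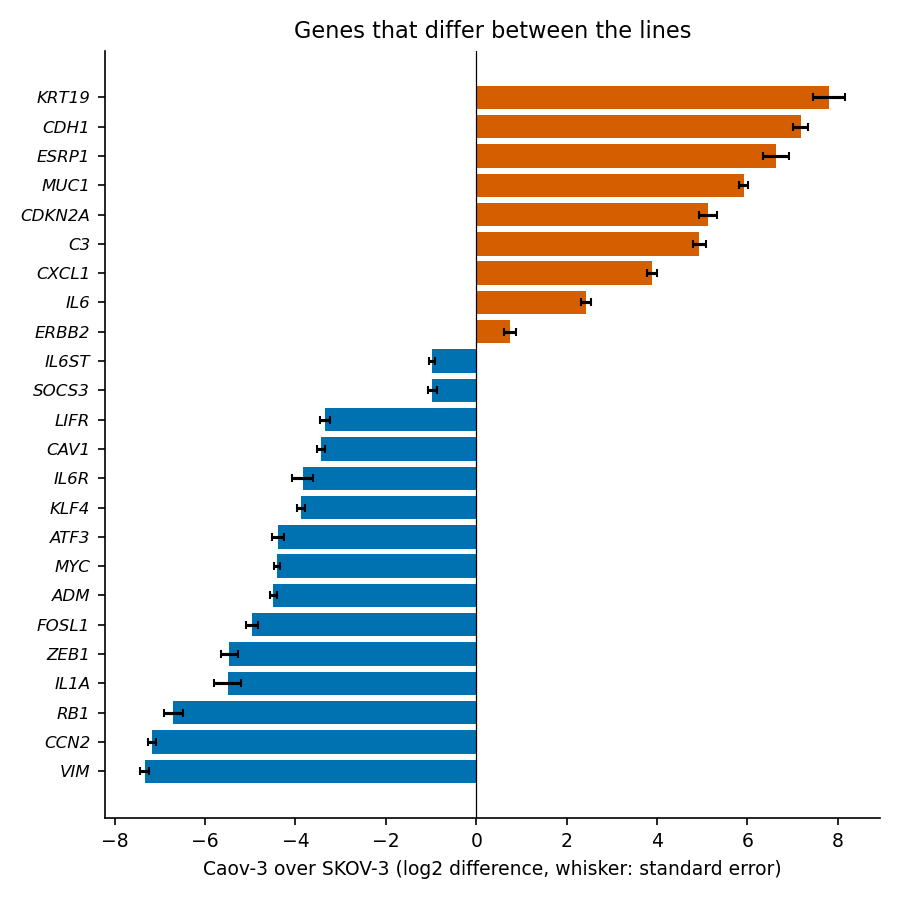
Bars give the limma log2 difference of Caov-3 over SKOV-3 for 24 genes named in the text, with whiskers for the standard error (3 arrays per line, 1 per treatment). Epithelial genes such as KRT19 (7.80) lie towards Caov-3, and VIM (-7.34), RB1 and MYC towards SKOV-3.

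By list, 17 of 20 epithelial and ovarian carcinoma markers were higher in Caov-3 and 0 lower, and the list was higher in limma's camera test with a preset correlation (adjusted p 0.000124), a call lost with an estimated correlation (adjusted p 0.839). Of 23 immediate early genes 18 were lower and 4 higher in Caov-3, among them FOSL1 at -4.97, ATF3 at -4.39 and the matricellular CCN2 at -7.18, and the list was lower in camera (adjusted p 0.000143), likewise lost with an estimated correlation (adjusted p 0.839). Among early response genes of IL-6 and STAT3 7 of 19 were higher and 6 lower, with KLF4 at -3.88 among the latter. Of NF-kB targets 8 of 19 were higher, such as CXCL1 at 3.89, and 6 lower, such as IL1A at -5.50. Acute phase proteins had 5 of 6 higher, C3 foremost at 4.94, and 1 lower. Interferon-stimulated genes had 7 of 19 higher and 8 lower, with high signals in both lines, ISG15 being at 37906 in untreated SKOV-3 and 27575 in untreated Caov-3.

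Survival and growth targets of STAT3 had 5 of 14 higher and 5 lower in Caov-3, receptor and signalling genes 6 and 7 of 20, and cell cycle genes 5 and 8 of 21. Hypoxia and glycolysis genes had 9 of 17 higher, with BNIP3, a mitophagy receptor, at 7.61, and 4 lower, with the vasodilator ADM at -4.49. Unfolded protein and amino acid stress genes had 6 of 18 higher and 10 lower, heat shock genes 0 of 9 higher and 6 lower, sterol synthesis genes 3 and 5 of 10, and drug transport and paclitaxel resistance genes 4 and 7 of 13, with ABCC3 at 3.31 and the tubulin gene TUBB2A at -2.70. Identity genes had 4 of 5 higher and 1 lower, leukocyte markers 1 of 4 higher (CD14), fibroblast and endothelium markers 3 of 3 higher, COL1A1 at 3.94 among them, and reference genes 5 of 11 higher and 3 lower. When adjusted over the list alone the counts were the same, apart from 10 higher in the hypoxia and glycolysis list and 6 higher among the reference genes.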

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

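None of the values in this part was tested, and the genes in it were picked out after their folds had been seen. Bacterial poly-A transcripts, which are added to each RNA sample before labelling and are no measure of the cells' own RNA, gave more signal on the IL-6 arrays than on the untreated array of the same line. Their geometric mean was 1.52 times the untreated level in SKOV-3 (1.5187) and 1.49 times in Caov-3 (1.4898). The amount added relative to the RNA was thus not equal between arrays by this measure, and the cause was not tested.

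For 4 genes the log2 fold stood opposite ways in the 2 lines, on 1 array per group. Since 92 genes stood opposite ways with IL-6 by at least 1.5-fold in both lines, where 58.0 were expected after matching on expression, such a gene alone carries little weight. STAT3 with IL-6 was at 0.92 in SKOV-3 and -1.58 in Caov-3, a difference of 2.5, but 2 of its 4 probe sets were at -0.07 and 0.00 in SKOV-3, where no opposite course is seen. The pseudogene NACA4P was at 2.24 and -1.58 with IL-6, a difference of 3.82, and at -0.77 and 2.68 with siltuximab, a difference of -3.45. CDK18 was at -1.11 and 2.40 with IL-6, a difference of -3.51, and GTF2IP20 at -2.69 and 0.62 with siltuximab, a difference of -3.32. These differences between the lines were not tested, and each rests in Caov-3 on the IL-6 array that had the low ACTB ratio.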

How the results depend on the processing

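The fits without the Caov-3 IL-6 array were chosen after seeing the data, and the other alternatives of this part were chosen before. The number of genes called between the lines stayed within 1.5 times of 8707 under each alternative, from 6288 to 8849, and was 7578 to 8673 with each treatment left out in turn, where the remaining arrays are assumed to vary alike. For the treatments limma called 0 genes under the pseudocount, filter, scaling, probe set, trend and block alternatives. With a line left out, only the other line's folds remain, with no test, and they are those of the report. Without the Caov-3 IL-6 array it called 3 genes for IL-6 and 3 for siltuximab plus IL-6 against untreated, and 0 for siltuximab plus IL-6 against IL-6 (833 at an unadjusted p under 0.05). That fit has 1 residual degree of freedom, and its lone IL-6 array is assumed to vary like the rest.

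Numbers of genes at least 2-fold apart are given in the order IL-6, siltuximab plus IL-6 against IL-6, and siltuximab plus IL-6 against untreated, each in SKOV-3 and then Caov-3. They were 237, 464, 117, 366, 215 and 123 as reported. A pseudocount of the median gave 28, 215, 5, 149, 21 and 18, and a filter at the 75th percentile gave 15, 139, 2, 112, 8 and 9. Both remove weight from dim genes by construction. No filter admitted dim genes and gave 1749, 1871, 1312, 1651, 1722 and 1551. The mean of all probe sets gave 124, 59 and 120 in SKOV-3. Genes the same way in both lines, 81 with IL-6 and 28 with siltuximab, became 37 and 3 with the median pseudocount, 759 and 574 without a filter, 27 and 1 with the 75th percentile filter, and 11 and 2 at the stricter 2-fold threshold. Without a pseudocount siltuximab gave 48, and the mean of probe sets gave 49 with IL-6. These numbers therefore depended on how dim genes were treated. The comparisons that use the Caov-3 IL-6 array depended on it less, with 139 and 112 genes left under the 75th percentile filter against 15 and 2 in SKOV-3.

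Genes higher with IL-6 in one line had, with siltuximab in the other and relative to all genes, a median of 0.08 (SKOV-3 genes in Caov-3) and of 0.01 (Caov-3 genes in SKOV-3). In that order the values were 0.106 and -0.006 with the 75th percentile filter, 0.023 and 0.025 after cyclic loess, 0.178 and 0.023 with the mean of probe sets, and -0.026 and 0.055 at the 2-fold threshold. For the SKOV-3 genes it was 0.036 after quantile normalization and 0.099 without probe sets ending in _x_at or _s_at, and for the Caov-3 genes -0.023 without a filter. The cause was not tested.

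The camera call for leukocyte markers with IL-6 was lost with an estimated correlation (adjusted p 0.953), a median pseudocount (0.0689), no filter (0.443), quantile normalization (0.11), cyclic loess (0.113) and without the Caov-3 IL-6 array (0.133), and had no value under the 75th percentile filter or the mean of probe sets, which left too few genes. The range over its alternatives was 0.0325 to 0.953. That for interferon-stimulated genes with siltuximab was lost with an estimated correlation (0.991), no filter (0.0808), the mean of probe sets (0.129), without probe sets ending in _x_at or _s_at (0.0602) and without the Caov-3 IL-6 array (0.625), over a range of 0.00016 to 0.991. Immediate early genes and epithelial markers between the lines were lost with an estimated correlation alone (0.839 each). The cause was not tested.

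Some genes changed sign. With the mean of all probe sets, the IL-6 fold in Caov-3 became -0.34 for ERBB2, -0.52 for FUBP3, -0.56 for NFATC2IP, -1.10 for ACSL4, -0.35 for CCND1, -0.42 for SLC7A11, -0.41 for STMN1, -0.49 for TOP2A and -0.33 for PRKACA, and in SKOV-3 -0.26 for XBP1. With siltuximab in Caov-3 it became 1.03 for ERBB2, 0.24 for XBP1, 0.59 for NFATC2IP, 1.20 for ACSL4, 0.34 for SLC7A11, 0.19 for STMN1 and 0.58 for TOP2A, and in SKOV-3 -0.12 for LIFR. Between the lines ACSL4 became -0.92, OAS3 -0.48 and STMN1 0.04. Without probe sets ending in _x_at or _s_at, ACSL4 became -1.66 with IL-6 in Caov-3 and -1.26 between the lines, and with siltuximab in Caov-3 ABCC3 became 0.18 and NFKB2 -0.46. Over the alternatives run for them, 2868 log2 folds were within the spread of genes of their expression, 219 moved beyond it and 21 reversed. List medians were run under quantile normalization, cyclic loess and the mean of probe sets, where 164 stayed within the spread of random lists and 56 moved beyond it. Some changed sign. With the mean of probe sets in Caov-3, sterol synthesis went from 0.078 to -0.258 with IL-6 and from -0.136 to 0.25 with siltuximab, identity genes from 0.105 to -0.291 and from -0.114 to 0.141, cell cycle genes with IL-6 from 0.082 to -0.101, and drug transport genes with siltuximab from -0.186 to 0.031. Receptor and signalling genes with IL-6 went from -0.075 to 0.088 in SKOV-3 and from 0.04 to -0.081 in Caov-3, where they were at 0.127 after quantile normalization. In SKOV-3 drug transport genes with IL-6 went from -0.202 to -0.015. After quantile normalization reference genes with IL-6 in Caov-3 went from -0.144 to 0.013. The cause was not tested. Between the lines a named gene lost its call in 15 cases and gained one in 8. The 2 settings that reversed genes bring in other probe sets. On the Caov-3 IL-6 array, over 5767 genes with at least 2 probe sets, the brightest had a median log2 fold of 0.08 and the next -0.05, while in SKOV-3 these were -0.02 and 0.01, and why they part was not tested.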

Other observations

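In this part the tests on exchanged lines, on further probe sets, on the ACTB ratio and on other splits of the arrays, and the comparison with genes of the opposite pattern, were chosen only after their results were seen. SOCS3, C3, ELF3 and HK2 each stood above untreated with IL-6 and below that with siltuximab in both lines, though the 2 folds of a line share the IL-6 array. How many genes share this course by sign alone was not counted, so that these genes do not by themselves show a reversed response to IL-6. HK2 was at 0.17 and 0.54 with IL-6 in SKOV-3 and Caov-3, and ELF3 at 0.38 and 0.36. Caov-3 had the higher IL6 signal (3620) while its IL6R signal was 41.6, below the median of its arrays.

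ERBB2 was not higher on the arrays labelled SKOV-3, a line known for its amplification. Of 6 neighbouring genes searched, 4 were measured, and their median log2 difference towards SKOV-3 was 0.432, with PNMT at 0.71, PGAP3 at 0.15, MIEN1 at 0.72 and GRB7 at -1.10, and 0 of them 2-fold higher. This argues against a faulty ERBB2 probe set as the cause, since the neighbours were not amplified in signal either. CDKN2A, deleted in SKOV-3, was higher on the arrays labelled Caov-3 by 5.13, which argues against an exchange of the lines. Cells behind the SKOV-3 arrays that lack the amplification remain a candidate explanation, and DNA, which would settle the identity of the line, was not analysed here.

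On the Caov-3 IL-6 array 207 genes stood at least 2-fold below both other Caov-3 arrays, against at most 23 on any other array. Among genes above the median in expression the count was 59, against 0 to 3 on the other arrays. The bound of 1.5 times set in advance was wrong, since this count defines the pattern and an array with greater noise would pass it too. The counts argue against noise of the size seen on the other arrays, but greater noise on this array stays open. In SKOV-3 187 of the 207 genes were measured, with a median IL-6 fold of 0.111, at percentile 100 of matched random sets, which argues against a response that both lines share. Further probe sets of 89 of these genes had a median of -0.217 (bootstrap interval -0.445 to -0.104), which argues against loss of the whole transcript for all of them but leaves it open for the 29 that were lower by at least 1.5-fold, the more so as folds of 2 probe sets of a gene correlated at 0.104. The ACTB 5' to 3' ratio of 0.494 lay below the 0.643 to 0.766 of the other arrays, so that poorer RNA may explain part of the pattern. A response of Caov-3 alone was not tested and stays open, as the array is the only one of its group.

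SOCS3 was higher with IL-6 and lower with siltuximab in both lines, and 15 genes of 10291 reached, in both lines, SOCS3's weaker fold of the 2 lines in each step (0.461 and -0.275), where 9.2 were expected of independent lines. That excess had been set in advance as evidence against chance in single arrays, but the bound was wrong, since genes with this course in one line and the opposite course in the other exceeded their expectation by more, 79 against 25.4. In a different count, of genes at least 1.5-fold the same way in 1 comparison, simulated unchanged arrays gave 23.6 where independent lists gave 6.3. Chance and a response therefore cannot be told apart for SOCS3 from single arrays. Of its 3 further probe sets, 1 dim one followed the course, with IL-6 folds of 0.73 and 0.79, and 2 did not. Of these, 1 was at -0.23 in SKOV-3 and 0.01 in Caov-3 with IL-6. The other took the opposite course in Caov-3, at -0.94 with IL-6 and 0.85 with siltuximab.

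Between the lines 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 8669 genes without a treatment block, and the highest of the other splits gave 0. Each of the other splits mixed the lines, which put the line difference into the residual and left little room for a call. That 0 therefore does not speak for or against chance.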
